A study of Homo sapiens with 6 samples.

How the data were processed

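The samples were Jurkat T-REx cells, a human leukaemic T cell line carrying a tetracycline-responsive repressor so that an introduced gene can be switched on with doxycycline. Lines expressed 3xFLAG-tagged wild-type ZNF335 (WT), 3xFLAG-tagged ZNF335 with the substitution R1092W (named bloto in the labels), or no tagged protein (control). ZNF335, called Zfp335 in mouse, is a C2H2 zinc finger transcription factor. Per the labels' protocols, the lines were stable clones picked for a co-expressed fluorescent reporter, and expression was induced with doxycycline overnight. Chromatin was cut by sonication together with micrococcal nuclease and immunoprecipitated with the anti-FLAG M2 antibody. Libraries were size-selected to 200 to 500 bp and sequenced as single-end reads of 50 bp. The series has 6 samples: 3 ChIP samples and 3 input samples, with 1 library per condition. The antibody field of the bloto input also names the FLAG antibody, although its title and description call it input, and it was taken as an input.

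The data used were the authors' peak lists, 1 per ChIP sample. Per the submitters' processing notes, the tools were CASAVA 1.8.2, cutadapt 1.4.1, BWA, SAMtools and MACS2, and the genome build was hg19, which the headers of the WT and bloto lists also name. The versions of BWA, SAMtools and MACS2, the MACS2 cutoff and the choice of input for each ChIP are not given in the sources used here. The peak names contain "rmdup" and "SPMR", which are read here as removal of duplicate reads and a per-million-reads signal option. In the deposited lists each peak has a fold (a ratio of ChIP to local background at the summit), a −log10 p-value, a −log10 q-value adjusted within its own list, a score equal to the whole part of 10 times that q-value column, and the offset of the summit. Peaks were called per ChIP sample against an input background, so no value combines different ChIP libraries. The fold, p-value and q-value of a peak are the authors' own, and they were used to describe, rank or filter peaks within a list. Because the q-value is adjusted within each list, the same p-value can have different q-values in different lists. Peak numbers ran without gaps in each list, and no rows of a list overlapped one another. Coordinates are given here on hg19, counted from 1.

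Read depth was recovered from the deposited fold and p-value columns. A MACS2 peak has fold (pileup + 1)/(background + 1), and its p-value is the upper Poisson tail of the pileup at that background, so the 2 columns together give both unknowns. The WT pileups came out as whole multiples of 1 scale, 0.856, in 634 of 634 peaks, and the bloto pileups as whole numbers in 174 of 174 peaks, with a tolerance of 0.001 reads. In each list 1 peak had more than 1 whole-number solution, and the closest was taken. On simulated lists of 300 peaks each, the same procedure recovered 100% of the reads for the WT settings and 100% for the bloto settings. The simulated lists were built with the same formulas, so they check the arithmetic and not whether the deposited columns follow these formulas. Their summit reads did not go as low as those of the deposited lists. A scale below 1 means that the ChIP was scaled down to its input, which gives 1.17 WT ChIP reads per input read. The steps of the bloto background gave 0.78 bloto ChIP reads per input read. The lowest background was shared by 13 WT peaks and 3 bloto peaks and was taken as the genome-wide background. Divided by the read extension of 146 bp found from the background steps, it corresponds to 8.67 WT ChIP reads per kb of the genome size used by the caller, and to 9.28 bloto ChIP reads per kb. The matching inputs came to 7.43 and 11.9 reads per kb. These depths assume that both lists were called with the same genome size. The single control peak is too little to fix a scale, so the depth of the control library is unknown.

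Peaks of different lists were called shared when they overlapped by at least 1 bp (checked with bedtools 2.31.1). Shares carry exact Clopper-Pearson 95% intervals, which cover counting error only and treat peaks as independent. To give the overlap of uniformly drawn positions, the bloto peaks were placed at random 1000 times on their own chromosomes, up to the last peak of any list. The placements took no account of mappable sequence or accessible chromatin, so they do not give the overlap of unrelated ChIP lists from the same cells. Medians of peak classes within the WT list were set against 10000 random classes of the same sizes, and their differences carry 95% bootstrap intervals over peaks (10000 draws). With 1 library per condition no difference between conditions has a replicate check, and no p-value between conditions is given. Analyses used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and figures matplotlib 3.10.9.

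The counts of peaks, the shared shares, the shares per quartile of fold and the difference in fold, with a rule for the peaks to be named and most alternatives, were fixed before the data were examined. Read recovery, the comparisons of width, summit reads, summit positions, top ranks and chromosomes, and 2 alternatives (a −log10 p of at least 10 and quartiles of summit reads) were added after the lists had been seen. The peaks to be named were every control peak, the 15 WT peaks of highest fold, the 10 WT peaks of highest fold without an overlapping bloto peak, up to 10 bloto peaks without an overlapping WT peak, and the 10 bloto peaks of highest fold with one. Some of these are summarised as ranges. Peaks named for their summit positions, or as neighbours or counterparts of another peak, lie outside this rule unless they also meet it and were chosen after their values were seen. Alternatives covered a −log10 q of at least 5, a fold of at least 5, other definitions of a shared peak, merged rows, removal of peaks overlapping a control peak and lists of equal length. Promoter shares, gene assignment with the fixed gene lists, and motif searches had also been planned. They need the hg19 sequence and annotation, which were not used here, so peaks are named by position and no gene is assigned to them.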

Results

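FLAG-tagged ZNF335 was mapped by anti-FLAG ChIP-seq in Jurkat T-REx cells. One clone line carried the wild-type protein, another carried the bloto form with the substitution R1092W, and a control line had no tagged protein. The comparisons ask where peaks were called in tagged and in untagged cells, and how the peak lists of the WT and the bloto line differed. With 1 clone and 1 library per form, a difference cannot be assigned to the substitution. The series title concerns the recognition of separate motifs by separate zinc finger arrays of this protein, and the bloto substitution is the variant the study tested in these cells. The WT list held 634 peaks, the bloto list 174 peaks and the control list 1 peak. The depth recovered from the lists was 8.67 ChIP reads per kb of genome for WT and 9.28 for bloto, so the bloto library was the deeper one by a factor of 1.07. The depth of the control library is unknown.

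Anti-FLAG signal was enriched at 634 discrete sites in cells with tagged WT protein, and none of them had a counterpart in the list from untagged cells. The only control peak lay at chr11:66189134-66189404, with a fold enrichment of 4.59 over its local background, and 0 of the 634 WT peaks overlapped it. The nearest peak of either tagged line began 16.7 kb away, at chr11:66206098, where the WT fold was 19.2 and the bloto fold 8.67. Here and below, each fold is relative to the local input background of its own list. Folds of the 2 lists are therefore not compared in size. WT peaks occurred on all 23 chromosomes that held any peak, with 63 on chromosome 1, 54 on chromosome 2 and 52 on chromosome 19, and 11 on the X chromosome. They were narrow, with a median width of 286.5 bp and a range of 146 to 1549 bp. The median WT fold was 6.71, the highest was 30.7, and the number of ChIP reads covering a WT summit ranged from 12 to 97 with a median of 26. The bloto peaks had a median width of 342.5 bp, a median fold of 8.57 and 11 to 68 reads at the summit, with a median of 33. The medians of the 2 lists cover different sites. The 166 WT peaks that overlapped a bloto peak had medians of 619.5 bp and 61 reads, and the 468 others 236 bp and 23 reads. Each condition has 1 library, so the number of peaks per line has no replicate error. The control peak had a −log10 p of 13.1 but a −log10 q of only 4.08, because q-values were adjusted within each list, and it was absent at a −log10 q or a fold of at least 5, which left 0 control peaks.

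The 15 strongest WT sites all had a bloto peak. The WT peak of highest fold, chr19:3626622-3627319, reached a fold of 30.7 with 87 reads at its summit, followed by chr19:51307615-51308312 with a fold of 30.4 and 92 reads. The next were chr2:231921198-231921758 with a fold of 25.6, chr11:34072689-34073426 with 24.5, chr8:74205479-74206668 with 24.5 and chr6:31620195-31620854 with 23.4. The peaks at chr17:42976435-42977219, chr2:26467284-26467931, chr2:95787384-95787985 and chr19:1848299-1848868 had folds of 23.1, 22.8, 21.6 and 21.3. The first 15 WT peaks by fold, down to a fold of 20.3, overlapped a bloto peak in 15 of 15 cases (exact 95% interval 78.2% to 100%). The same held for 50 of the first 50 (92.9% to 100%), and for 92 of the first 100 (84.8% to 96.5%).

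Nearly all bloto peaks overlapped a WT peak. Of the 174 bloto peaks, 172 overlapped a WT peak, which is 98.9% (exact 95% interval 95.9% to 99.9%). The share depended on the definition: it was 60.3% (105 of 174) with reciprocal overlap of at least 50%, and 79.3% against only the 174 WT peaks of highest fold. Uniform random placement of the bloto peaks on the same chromosomes gave a mean of 0.031 overlapping peaks and at most 2 in 1000 placements. The overlap of unrelated ChIP lists from these cells is not known. The strongest bloto peaks were chr20:36156159-36156740 and chr9:101984242-101984747, each with a fold of 18.8 and 50 reads at the summit. They were followed by chr11:34072828-34073442 with a fold of 18.5, chr19:51307633-51308320 with 18.4 and chr18:56806753-56807131 with 18.1. The bloto peak with the most reads, 68, was chr20:44600390-44601053, with a fold of 16.5. It lay within the WT peak chr20:44600219-44601194, which had a fold of 19.3 and 89 reads. Of the 10 strongest shared bloto peaks, 3 belonged to the 15 strongest WT peaks. The 2 bloto peaks without a WT counterpart had fewer summit reads than the median bloto peak, which had 33: chr2:47206043-47206205 had a fold of 8.07 with 18 reads, and chr1:57441061-57441206 had a fold of 4.79 with 15 reads. The nearest WT peak lay about 3137 kb from the latter and about 4617 kb from the former.

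In the other direction, most WT sites had no bloto peak. Only 166 of the 634 WT peaks overlapped a bloto peak, which is 26.2% (exact 95% interval 22.8% to 29.8%), and 468 did not. The strongest WT peak without a bloto peak ranked 57th by fold and lay at chr3:123303949-123304656, with a fold of 15.1 and 50 reads at the summit. Next came chr19:38145522-38145823 with a fold of 14.3 and 38 reads, and chr12:124950906-124951210 with a fold of 13.3 and 37 reads. The peak at chr22:51221951-51222205 had a fold of 12.8, chr17:6541426-6541815 had 12.5 and chr12:133338309-133338673 had 11.9. The remaining peaks of the 10 strongest were chr17:27169835-27170243 and chr12:6560573-6561425, with 45 and 48 reads, and chr5:134761586-134761871 and chr16:686733-687042, with folds of 11.3 and 11.2. At this depth a missing peak means that the site did not pass the authors' cutoff in the bloto library, not that binding was absent. A stricter definition of sharing, reciprocal overlap of at least 50%, left 105 shared sites, which is 16.6% of the WT peaks, while 75.9% of the 174 WT peaks of highest fold, a list as long as that of bloto, were shared.

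The share of WT peaks with a bloto peak was far higher in the highest quartile of WT fold than in the others. In the lowest quartile of WT fold, from 2.37 to 5.60, 5 of 159 peaks were shared, which is 3.14% (exact 95% interval 1.03% to 7.19%). The second quartile had 11 of 158 shared, 6.96% (3.53% to 12.1%). The third had 25 of 158, 15.8% (10.5% to 22.5%). The fourth, from a fold of 9.47 upwards, had 125 of 159, 78.6% (71.4% to 84.7%), so its interval lies above those of the other quartiles. Within the WT list, shared peaks had a median fold of 12.9 and WT-only peaks one of 6.17, a difference of 6.72 (bootstrap 95% interval 5.13 to 7.60). This exceeded the difference in 10000 of 10000 random classes of the same sizes, the highest of which was 1.14. Random classes ignore that a shared peak had to pass a cutoff in a second library. Stronger sites would pass it more readily in any second library, so this comparison does not show an effect of the bloto form. Shared WT peaks were also wider, with a median of 619.5 bp against 236 bp, and had more reads at the summit, with a median of 61 against 23. These intervals describe peaks of 1 WT library and have no replicate check. The shares of the lower quartiles depended on the setting: a permitted gap of 1000 bp gave 11.3% and 13.3% in the first and the second, reciprocal overlap gave 2.52%, 1.27% and 6.96% in the first, the second and the third, so that the first lay above the second, a −log10 p of at least 10 gave 24.8% in the third, and quartiles of summit reads gave 0.629% and 1.27% in the first and the second.

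**Figure D1:**
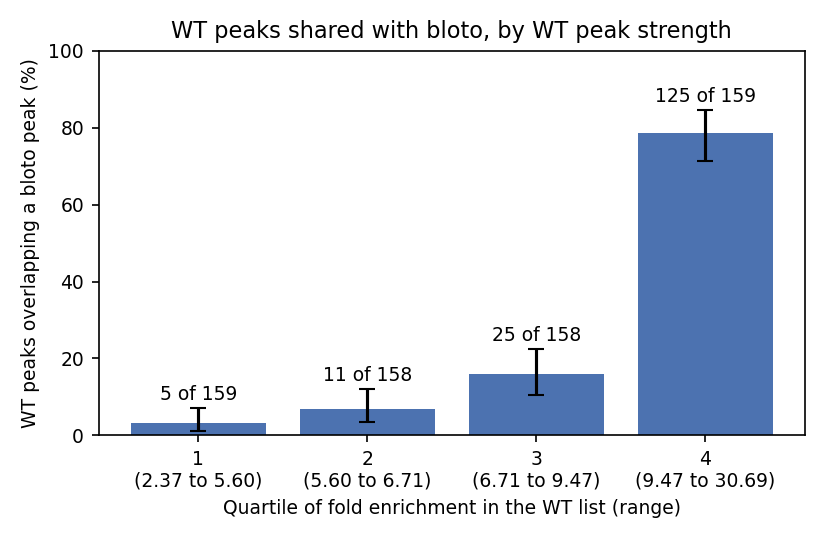
Share of WT peaks overlapping a bloto peak (y axis, percent) in each quartile of the WT list's fold enrichment (x axis, with the range of fold). Bars give the share, error bars the exact 95% binomial interval and the numbers the shared peaks of each quartile; the share is 78.6% in the highest quartile and at most 15.8% in the others.

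**Figure D2:**
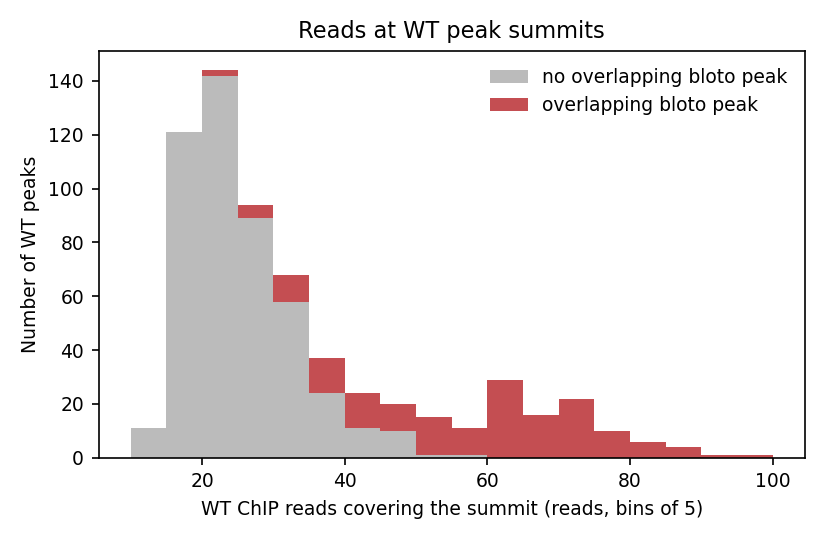
Number of WT peaks (y axis) by the WT ChIP reads covering the summit (x axis, bins of 5 reads), stacked by whether a bloto peak overlaps (red) or not (grey). All peaks with 60 reads or more overlap a bloto peak (45 of 45 with 60 to 69 and 44 of 44 with 70 or more), and none of the 132 peaks below 20 reads does.

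At sites with a peak in both lists, the summits lay close together. Across the 166 shared sites, the WT summit and the summit of the bloto peak with the most reads lay a median of 18.5 bp apart (interquartile range 6 to 42.8 bp). At 128 sites, 77.1% (exact 95% interval 69.96% to 83.3%), the distance was at most 50 bp, and at 13 sites it exceeded 100 bp. The largest distance, 482 bp, was in the WT peak chr6:5260920-5262166. This WT peak had its summit at 5261130, and 2 bloto peaks lay within it. The bloto peak at chr6:5260964-5261212 had its summit 11 bp from that of WT and 26 reads, and the one at chr6:5261369-5261952 had 46 reads. In all, 6 WT peaks overlapped 2 bloto peaks each. Another was chr17:47784667-47785884, with a WT fold of 20.7, where the bloto folds were 10.2 and 4.70. Further WT peaks with displaced bloto summits were chr16:1358954-1359793, by 383 bp, and chr4:2010464-2011196, by 278 bp. Summit positions have no replicate error here.

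**Figure D3:**
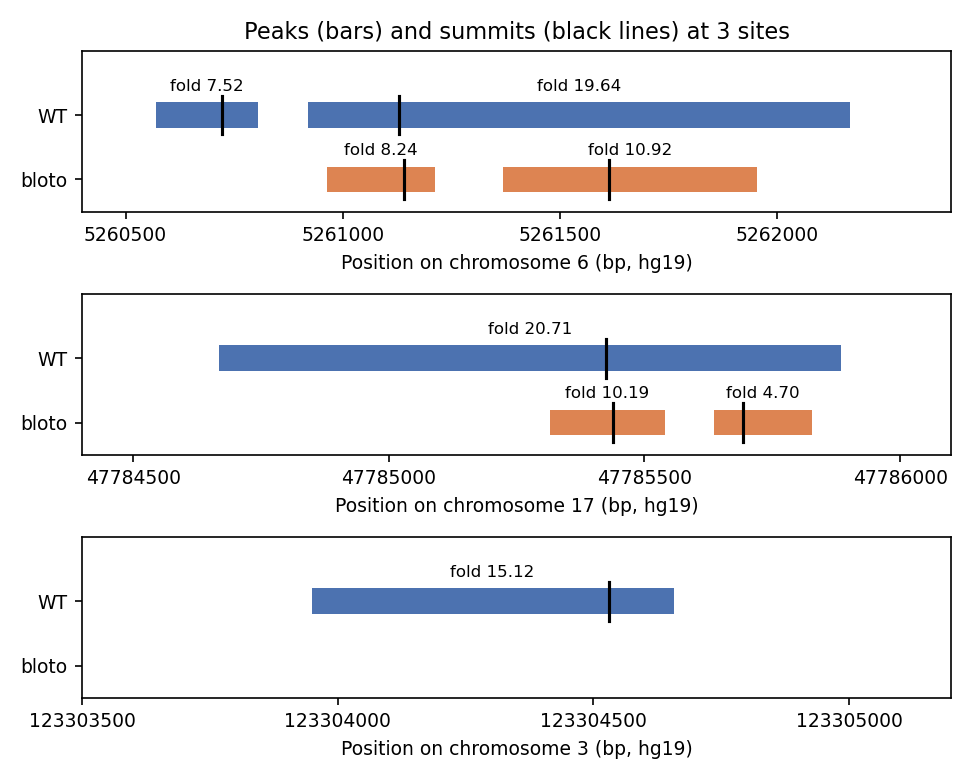
Peaks (bars, WT blue and bloto orange) and summits (black lines) along hg19 positions in bp (x axis) at a WT peak spanning 2 bloto peaks on chromosome 6, another on chromosome 17, and, on chromosome 3, the WT peak of highest fold among those without a bloto peak. Numbers above the bars are fold enrichments. On chromosome 6 the stronger bloto peak, with a fold of 10.9, has its summit 482 bp from the WT summit.

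WT sites without a bloto peak were spread over the chromosomes. On chromosome 2, 21 of 54 WT peaks were shared, 38.9% (exact 95% interval 25.9% to 53.1%), and on chromosome 3, 6 of 42, 14.3% (5.43% to 28.5%). Chromosome 14 kept 10 of 25 and the X chromosome 2 of 11. When the shared peaks were reassigned at random among the WT peaks, 88.6% of 10000 reassignments were at least as uneven over the 23 chromosomes as the data. No difference between chromosomes in the share of retained sites was therefore detectable with these numbers of peaks.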

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

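The settings with a −log10 p of at least 10 and with quartiles of summit reads were chosen after seeing the data. Of 76 values recomputed under alternatives, 54 moved by no more than the interval of the reported value or, for counts of peaks, by no more than 1.5 times. The other 22 moved further. The 54 include every value from merging rows and from removing peaks over a control peak, which could not move. Only the difference in median fold has a direction that could turn, and it did not. No paired analysis was possible because each condition has 1 library, and for the same reason no replicate could be left out. Merging rows and removing peaks over a control peak changed nothing, since no rows and no control peak overlapped. With a −log10 q of at least 5, 0 control peaks remained, the shared part of the WT peaks was 29.98% and that of the fourth quartile of fold 85.3%. With a fold of at least 5, 0 control peaks remained. A −log10 p of at least 10 gave 30.9% for all WT peaks, 24.8% for the third quartile and 85.6% for the fourth. Reciprocal overlap of at least 50% gave 16.6% of WT and 60.3% of bloto peaks, and 1.27%, 6.96% and 55.3% in the second, the third and the fourth quartile. With summits at most 100 bp apart, 88.5% of bloto peaks were shared. Allowing a gap of up to 1000 bp gave 30.3% of WT peaks, 11.3% and 13.3% in the first and the second quartile, and a difference in median fold of 4.99. With the WT list limited to the 174 peaks of highest fold, 75.9% of WT and 79.3% of bloto peaks were shared. Quartiles of recovered summit reads gave 0.629%, 1.27% and 85.5% in the first, the second and the fourth quartile. The cause of these moves was not tested. In each setting that had quartiles, the highest stayed above the others. Promoter, gene, gene list and motif results were not run. No setting varied the depth, and the depth of the control library is unknown.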

Other observations

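All tests in this part were chosen after the peak lists had been seen, and so were the sites named in it except chr3:123303949-123304656. The number of WT peaks fell from 238 with 20 to 29 reads at the summit to 105, 44 and 26 in the next steps of 10 reads, was 45 at 60 to 69 reads, and the remaining 44 peaks spread over 70 to 97 reads. The 26 peaks of 50 to 59 reads against 45 of 60 to 69 gave an exact binomial p of 0.0319 (two-sided, 1 comparison picked after seeing the counts). All peaks of 60 reads or more had a bloto peak (45 of 45 and 44 of 44), as had 24 of 26 with 50 to 59 reads, 23 of 44 with 40 to 49, 23 of 105 with 30 to 39, 7 of 238 with 20 to 29 and 0 of 132 below 20.

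At the 166 shared sites the bloto signal was lower than the WT signal. After scaling to equal depth and subtracting the local background, the bloto reads at the summit were a median of 0.54 of the WT reads (interquartile range 0.46 to 0.62, range 0.24 to 0.95), and lower than WT at every one of these sites. This ratio covers only sites called in both lists, so the 2 bloto peaks without a WT peak are left out. If the background were that of WT, 54 of the 468 other WT sites would lie under 0.35. That value is the fifth percentile at shared sites of 50 WT reads or more. On the same assumption chr3:123303949-123304656 would lie under about 0.21. A higher bloto background would raise these limits. They follow from the call rule at sites picked for having no bloto peak, without counting noise or a minimum width. They therefore do not show a greater loss at these sites than at the shared ones. Spearman's rho between the libraries across these 166 sites, which are not independent replicates, was 0.82 for summit reads (the largest of 10000 shuffles was 0.32) and lower, 0.63, for fold. The lowest ratio, 0.24, was at chr2:219536715-219537208, with 69 WT and 19 bloto reads, and the highest, 0.95, at chr14:77787413-77787565, with 28 and 26. These are comparisons of 1 library with 1 library, from separate clones.

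The smaller number of bloto peaks was set against depth, cutoff and background. The bloto ChIP library had 1.07 times the WT reads per kb, which argues against a shallower library. Of the 634 WT peaks, 614 reached the lowest −log10 p of the bloto list, 6.76, which argues against a stricter cutoff. The local bloto background, at equal depth, was measured only where a bloto peak was called, with an interquartile range of 0.55 to 1.07 times that of WT and a range of 0.29 to 3.92, so a higher background at the 468 other WT sites stays open. The level of tagged protein in each clone, the yield of the immunoprecipitation and the substitution itself stay open, since 1 clone and 1 library per form confound them.

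A candidate explanation for the missing sites is 1 common loss, as from less tagged protein or a poorer precipitation, that pushes the weaker WT sites under the cutoff. At shared sites of 50 WT reads or more the bloto signal was 0.54 of WT (113 sites, bootstrap 95% interval 0.52 to 0.56), and with the WT background this factor at every site predicted 390.4 WT peaks with a bloto peak (363 to 419 in 1000 simulations of counting noise) against 166 observed, 390.5 after a correction for read positions already taken, and at 20 to 49 reads 221.8 (198 to 251) against 53 after lowering the reads for the selection of peaks. With stricter calls the factor gave 252.3 (217 to 282) against 155 at a −log10 p of at least 10, 152.0 (133 to 170) against 125 at 15 and 103.6 (88 to 120) against 103 at 20; the sites of 50 reads or more, which supplied the factor, made up 113, 101 and 92 of the observed calls, so these are increasingly not separate tests. The gap rests on the assumed background and on the call rule. The simulations called a peak from the summit reads alone, with no minimum width. The narrowest bloto peak was 146 bp wide, so calls at weak sites may be over-predicted. At the highest bloto to WT background ratio of the shared sites, 3.92, set at every site, 170.3 were predicted (148 to 191), and 53.0 (34 to 74) at 20 to 49 reads. That ratio is an extreme, since its interquartile range at shared sites was 0.55 to 1.07. With the WT background a factor of 0.305 fitted to the calls alone gave 171.7 but lies under the interval of the strong sites. A common loss, alone or together with a higher background at the weaker sites, therefore stays open. So do a non-linear fall of occupancy with less protein, differences between clones and an effect of the substitution that differs between sites.

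WT peaks also came in neighbouring pairs at most 1000 bp apart: 45 pairs, with summits a median of 500 bp apart. A bloto peak was found at both members of 0 pairs, at 1 member of 26 pairs and at neither in 19. When bloto overlap was shuffled among WT peaks of like summit reads, a mean of 27.2 pairs had 1 member with a bloto peak. A mean of 0.41 pairs had both and 65.5% of 10000 shuffles gave 0, so too few were expected for the count of 0 to tell anything.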
